A study of Mus musculus with 2 samples.

How the data were processed

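H3K9ac ChIP-seq peak lists were analysed for mouse limb at embryonic day 11.5, in 1 group of 2 biological replicates. Per the labels, each replicate was a pool of limbs (109 and 88 embryos, mixed sexes), and the chromatin fragments were 300 to 500 bp long. Both are replicate pools of embryos of the same strain, so the spread between them covers differences between pools and preparations, not between single embryos.

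The authors deposited 4 peak lists in narrowPeak format on mm10, a list for each replicate, a pooled list and a replicated list. Per the text files deposited with the samples, the lists of the replicates and the pooled list were each called from filtered alignments, with the same pair of further alignment files in every case, and the replicated list was derived from the other 3 lists. The aligner, the peak caller, their versions and the rule behind the replicated list are not given in the sources used here. On inspection all 30298 peaks of the replicated list were peaks of the pooled list. All 25529 pooled peaks that overlapped a peak of each replicate by at least 50% of either peak were in it, and 25795 (85.1%) of its peaks overlapped both replicate lists by at least 1 bp. A further 1157 overlapped replicate 1 only, 3272 replicate 2 only and 74 neither.

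Each peak has 3 values from the authors. The signal is the narrowPeak signal value the authors deposited for each peak, and what it is relative to is not given in the sources used here. The −log10 p and −log10 q values are those the authors deposited, without a description of the test. The lowest −log10 p was between 2.00 and 2.05 in every list, so the lists include weak calls: 34.9% of replicate 1's peaks and 25.8% of replicate 2's had a −log10 q of at least 5, against 54.3% in the replicated list. Of the replicated peaks 1981 (6.54%) had a q above 0.05. Read counts were not used here and the depth is unknown, so a longer list may not be read as more marked sequence. Values of different lists were not compared with each other as levels.

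Peak positions were compared with the GENCODE mouse M21 annotation of GRCm38, the same assembly as mm10. Peaks within 1 kb of a transcript start of any gene were assigned to starts, then to exons, introns and intergenic sequence in this order. A protein-coding gene was called marked when a replicated peak lay within 1 kb of the start of any of its transcripts. Breadth was the number of bases within 5 kb on either side of the start of the gene record that replicated peaks covered, and was tested over marked genes. Distal peaks were replicated peaks over 2 kb from every annotated start, counted within 100 kb of the start of the gene record. A peak near several genes counted for each of them. Promoter CpG class came from the genome sequence of the 1 kb centred on the start of the gene record, and a promoter was CpG-rich with an observed over expected CpG ratio of at least 0.6 and a GC content of at least 50%. Peaks on sequences outside the chromosomes were left out of the location shares.

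The 21 gene lists, the tests, their backgrounds and the rule for naming genes were fixed before the data were examined. The 21 lists held 1900 entries. The ribosomal protein and chemosensory receptor lists, of 82 and 1481 genes, were taken from the annotation by name pattern. All gene names written out for the other lists were found in the annotation. Marking of a list was compared with that of all other protein-coding genes by Fisher's exact test. Breadth and distal peaks were compared with 100000 random lists of the same size by a permutation test, whose smallest p is 2e-05. All tests were two-sided, p-values were adjusted by the method of Benjamini and Hochberg over the 21 lists, and 0.05 was the threshold. These tests treat genes as units and describe these 2 pools, and they do not measure variation between animals. Shares have 95% Wilson intervals, and values per replicate are given as mean ± SD with n = 2. The rule allowed any member of the lists to be named, with priority to the 4 members with the highest signal and to unmarked members. Outside the lists it named the 15 genes with the most covered bases, the 10 with the highest signal at a start, the 10 with the most distal peaks and the 5 strongest unshared peaks of each replicate. The coverage of whole Hox clusters, the comparison of Hox clusters with runs of neighbouring genes, and the other genes that share a start peak were added after the data had been seen.

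The tests were tried on simulated data for 20000 genes. Of 200 simulated lists of 35 genes with no difference 5.5% fell below 0.05 in Fisher's exact test, and 99.0% did so when 90% of members were marked against 60% of the rest. In the permutation test 7.0% of 200 lists of 30 genes with no difference fell below 0.05, and 94.0% of 50 lists did so when their values were multiplied by 2.

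The alternatives were other overlap rules, a −log10 q of at least 5, equal numbers of top peaks, the pooled list, each replicate's own list, peaks overlapping both replicates, other windows, random lists matched on CpG content or on the number of nearby starts, and a stricter CpG class. Uniqueness of sequence was measured as the share of 36-base words that occur at a single place in the genome. The analysis used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9. Signal tracks and reads were not analysed here.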

Results

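Acetylation of histone H3 at lysine 9 (H3K9ac), a mark found at active promoters, was mapped by chromatin immunoprecipitation and sequencing in mouse limb at embryonic day 11.5. At this stage the limb bud is growing out, its axes are being patterned and the skeleton is starting to form. The series held 1 group of 2 biological replicates, made from pooled limbs of 109 and 88 embryos of both sexes of the B6NCrl mouse strain. There was no second tissue, stage or treatment, so the comparisons are between replicates, between parts of the genome and between groups of genes. Replicate 1 had 49262 peaks covering 24.5 Mb, and replicate 2 had 71826 peaks covering 33.2 Mb. The peaks called on both replicates together numbered 38244, and the list the authors named replicated held 30298 of these, covering 22.9 Mb or 0.840% of the genome. Read depth is unknown from the peak lists. The signal of a peak is the authors' value for that peak, has no error of its own, and is used here only to rank, describe and compare peaks within a list, the replicated list unless a replicate is named. Coordinates are those of mm10.

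Every member of the fixed list of limb transcription factors carried the mark. A gene was counted as marked when a replicated peak lay within 1 kb of one of its annotated transcript starts. All 37 limb transcription factors of the list were marked, in the replicated list and in each replicate, against 62.1% of other protein-coding genes (Fisher's exact test, two-sided, p = 3.46e-08, adjusted over 21 gene lists 2.42e-07). The highest signals of the list were at Prrx1 (35.5), a homeobox gene of early limb mesenchyme, Tbx15 (31.0), Twist1 (29.4) and Tbx18 (28.0). The Prrx1 peak spanned 163306908 to 163314455 on chromosome 1, over the start of the gene (ENSMUSG00000026586), and had signals of 30.6 and 41.5 in replicates 1 and 2. Genes of forelimb and hindlimb identity were both marked. Tbx5 of the forelimb had a signal of 13.1, and Tbx4 and Pitx1 of the hindlimb had 19.1 and 20.97. The lowest values of the list were at Alx1 (3.66) and Emx2 (5.34).

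Genes of the signalling pathways that drive limb outgrowth were marked in 32 of 34 cases (94.1%, odds ratio 9.76, Fisher's exact test, two-sided, p = 2.67e-05, adjusted p = 0.000112). The strongest were the BMP receptor gene Bmpr1a (26.8), the FGF feedback inhibitor Spry2 (25.7), the Hedgehog receptor and target Ptch1 (23.5) and the FGF receptor Fgfr1 (23.3). Fgf8 and Fgf4, ligands made by the apical ridge, had signals of 3.82 and 3.17, and the ectodermal ligands Wnt7a and Wnt6 had 3.01 and 2.63. Shh, which is made by a small posterior zone of the bud, and Wnt3, an ectodermal ligand, were the list's unmarked members. Shh had a peak at its start in replicate 2 only (signal 3.52), and Wnt3 had peaks in both replicates (3.11 and 3.204) but none in the replicated list. With peaks restricted to a −log10 q of at least 5 the signalling list fell to 70.6% marked and no longer differed from other genes (Fisher's exact test, two-sided, adjusted p = 0.113).

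Markers of the other cell types in a limb bud were mixed. In the apical ridge and ectoderm list 12 of 21 genes were marked, led by Tfap2a (11.9) and the cadherin gene Cdh3 (8.81), whereas Trp63, Krt5, Krt14 and Sp8 were not. In the cartilage and bone list 16 of 21 were marked, led by the chondrogenic regulators Sox9 (17.1) and Sox6 (15.4) and by the cartilage collagen gene Col2a1 (15.1). Ihh, Col10a1, Ibsp and Bglap, genes of maturing cartilage or bone, were among the 5 unmarked. In the muscle lineage list 9 of 18 were marked. The early regulators Six4 (20.4), Six1 (14.0) and Eya1 (9.18) led it, Pax3 and Myod1 had 3.17 and 2.33, and Myog, Myf5, Ttn and Acta1 were unmarked. In the endothelial list 8 of 16 were marked, with Fli1 (32.3) first and the VEGF receptor genes Kdr and Flt1 at 4.30 and 3.66; in the peaks of replicates 1 and 2 alone 75% and 81.2% of the list were marked. In the blood list 8 of 17 were marked, among them the erythroid regulators Klf1 (10.4) and Nfe2 (7.91). The globin genes Hba-x, Hba-a1, Hbb-y and Hbb-bh1 were unmarked. In the neural crest and Schwann cell list 6 of 10 were marked, led by Mpz (11.7), whose peak also lay at the start of Sdhc, and Mitf (7.202). None of these 6 lists differed from other genes (Fisher's exact tests, two-sided, adjusted p between 0.326 and 1). With a −log10 q of at least 5 muscle (27.8% marked) and blood genes (23.5%) were marked less often than others (exact adjusted p = 0.0479 and 0.0232), as were blood genes by the start of the gene record alone (17.6%, exact adjusted p = 0.00184). These settings were not matched on promoter CpG content. By the main rule 47.1% of blood genes were marked, against 27.5% in CpG-matched random lists (permutation test, two-sided, adjusted p = 0.147). For muscle genes the shares were 50% and 62.4% (permutation adjusted p = 0.477).

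Genes of unrelated tissues were mostly unmarked. Only 2 of 19 liver and gut genes were marked (10.5%, odds ratio 0.0715, Fisher's exact test, two-sided, p = 4.70e-06, adjusted p = 2.47e-05), namely Gata6 (6.40) and Foxa3 (12.9), whose peak also lay at the start of Sympk. The share was 21.1% in replicate 1's own peaks and 26.3% in replicate 2's, still below other genes (exact adjusted p = 0.00133 and 0.00138). In the pluripotency and germline list 3 of 17 were marked, Nanos3 (25.7), Dazl (3.71) and Pou5f1 (2.69), with an odds ratio of 0.130 (exact p = 0.000227, adjusted p = 0.000597). In the list of adult lymphocyte genes 3 of 15 were marked, Lck (5.86), Zap70 (3.50) and Foxp3 (9.78), whose peak also lay at the start of Ppp1r3f (odds ratio 0.152, exact p = 0.00188, adjusted p = 0.00439). Their share was 26.7% and 33.3% in the peaks of replicates 1 and 2 alone. Central neuron genes were marked in 7 of 20 cases (odds ratio 0.328, exact p = 0.0188, adjusted p = 0.0329), led by Rbfox3 (5.42) and Dlx2 (4.24). That difference was lost in the peaks of replicate 1 alone (50% marked, exact adjusted p = 0.347) and of replicate 2 alone (55%, exact adjusted p = 0.425). It was also lost with a start window of 2 kb (40%, exact adjusted p = 0.066). The difference held with a −log10 q of at least 5 (5% marked, exact adjusted p = 1.18e-05). It also held by the start of the gene record alone (20%, exact adjusted p = 0.00184) and with peaks in both replicate lists (25%, exact adjusted p = 0.00447). Heart genes were marked in 6 of 14 cases (exact adjusted p = 0.273), led by Myl4 (27.6), whose peak also lay at the start of Cdc27, and Hcn4 (9.55). They were marked less often than others with a −log10 q of at least 5 (21.4%, exact adjusted p = 0.0234), with peaks in both replicate lists (28.6%, exact adjusted p = 0.0394) and within 500 bp (28.6%, exact adjusted p = 0.0385). Of 1481 olfactory, vomeronasal and trace amine receptor genes only Vmn1r4 (9.94) and Olfr94 (2.68) were marked, and the Vmn1r4 peak also lay at the start of Nt5c3. This share of 0.135% was 0.405% and 0.608% in the peaks of replicates 1 and 2 alone.

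The cell cycle, housekeeping and ribosomal protein lists were marked almost without exception. This held for 20 of 20 cell cycle genes (exact p = 9.38e-05, adjusted p = 0.000328), led by Cdk1 (21.1) and the ribonucleotide reductase gene Rrm2 (20.02). It held for 19 of 19 housekeeping genes (exact p = 0.000164, adjusted p = 0.000492), from Actb (38.2) down to the X-linked Hprt (5.80) and Pgk1 (5.27). It also held for 80 of 82 ribosomal protein genes (odds ratio 24.5, exact p = 1.67e-14, adjusted p = 1.76e-13), led by Rps19 (31.5) and Rps6 (30.9), with Rpl10l and Rpl39l unmarked. Among the 21 lists 7 were marked more often and 5 less often than other genes at an adjusted p below 0.05, all by two-sided tests. Against random lists with matched promoter CpG content, the limb transcription factors and limb signalling genes were still marked more often (86.3% and 79.5% expected, permutation test, two-sided, adjusted p = 0.0112 and 0.0246). So were the ribosomal protein and housekeeping genes (90.5% and 84.0% expected, permutation adjusted p = 0.0112 and 0.0367). The cell cycle list did not pass (93.0% expected, permutation adjusted p = 0.705). It was already fully marked, the highest possible share, so that test could not have called it higher. The lymphocyte list was no longer lower (30.8% expected, permutation adjusted p = 0.705). The central neuron, liver and gut, pluripotency and chemosensory lists were still lower (77.8%, 50.1%, 64.2% and 10.4% expected, permutation adjusted p = 0.00105 each).

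**Figure D1:**
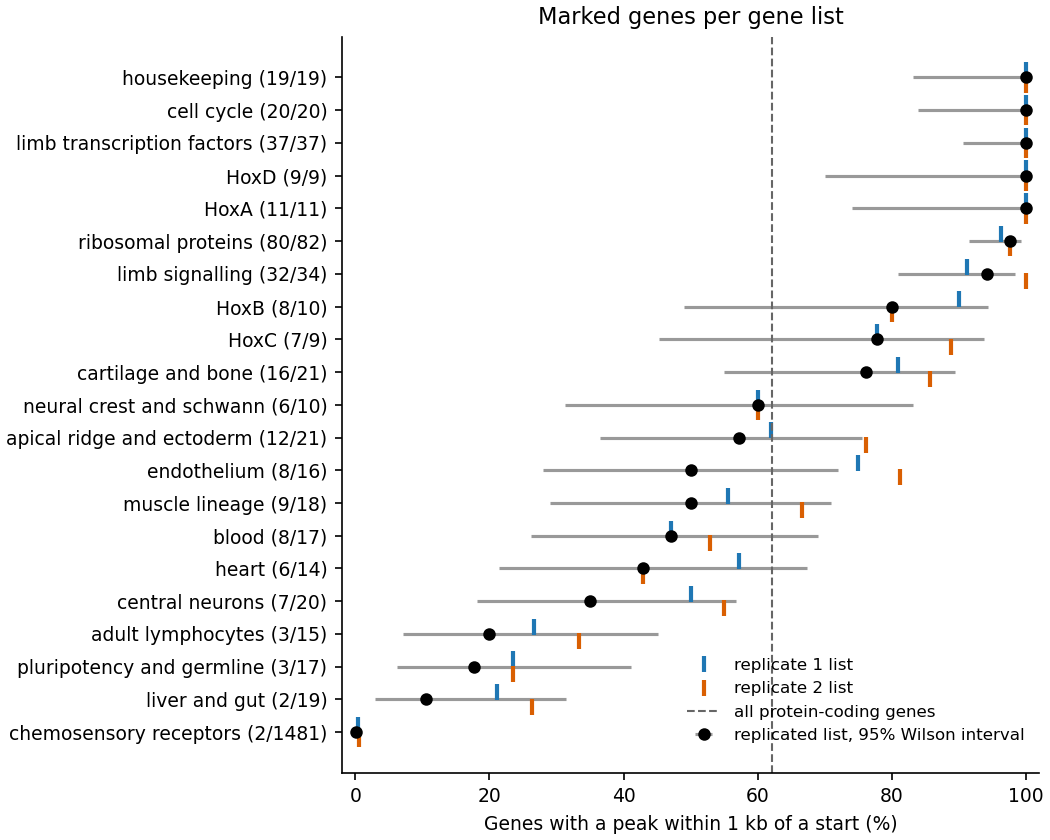
Percentage of each gene list's members with a replicated H3K9ac peak within 1 kb of a transcript start, with 95% Wilson intervals and the values of replicates 1 and 2 as ticks. Limb transcription factors sit at 100% and liver and gut genes at 10.5%, with other protein-coding genes near 62%.

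The Hox genes, which set positional identity along the limb, were marked to different degrees in their 4 clusters. The mark covered 57.1% of the HoxA cluster, 41.8% of HoxD, 35.7% of HoxC and 8.54% of HoxB, with replicate values of 58.2% ± 3.03, 41.6% ± 2.53, 36.2% ± 5.83 and 10.1% ± 2.91 (mean ± SD, n = 2). The widest HoxA peak reached from 52231404 to 52247469 on chromosome 6, a stretch of 16066 bp that spanned Hoxa10 and Hoxa11 and adjoined the start of Hoxa9, with a signal of 39.9. The widest HoxD peak, from 74690875 to 74701096 on chromosome 2, covered 10222 bp over Hoxd9 and Hoxd10 with a signal of 21.1. The genes that pattern the digits, Hoxa13 and Hoxd13, had signals of 16.6 and 14.5, while at the opposite end of these clusters Hoxa1 and Hoxd1 had 4.96 and 3.50. The widest HoxC peak (4886 bp) lay at Hoxc11, and the widest HoxB peak (1870 bp) at Hoxb2.

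By promoter marking, all 11 HoxA genes (Fisher's exact test, two-sided, p = 0.00915, adjusted p = 0.0192) and all 9 HoxD genes (exact p = 0.0163, adjusted p = 0.0312) carried the mark, as did 7 of 9 HoxC and 8 of 10 HoxB genes (exact adjusted p = 0.55 and 0.393). Hoxc12, Hoxc13, Hoxb1 and Hoxb13 were unmarked. The start peak of 5 HoxA and 4 HoxD genes also lay at the start of another gene, so these genes are not independent units. The marking p-values may therefore be too small, and marking was not compared with runs of neighbouring genes. In each replicate's own peaks all 9 HoxD genes were again marked, but the comparison no longer passed (exact adjusted p = 0.0596 for replicate 1 and 0.0642 for replicate 2). Against random lists with matched promoter CpG content neither HoxA nor HoxD stood out (92.0% and 92.5% expected, permutation test, two-sided, adjusted p = 0.92 and 1). That test could not have shown an excess for them, since even full marking, the highest possible share, did not pass.

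**Figure D2:**
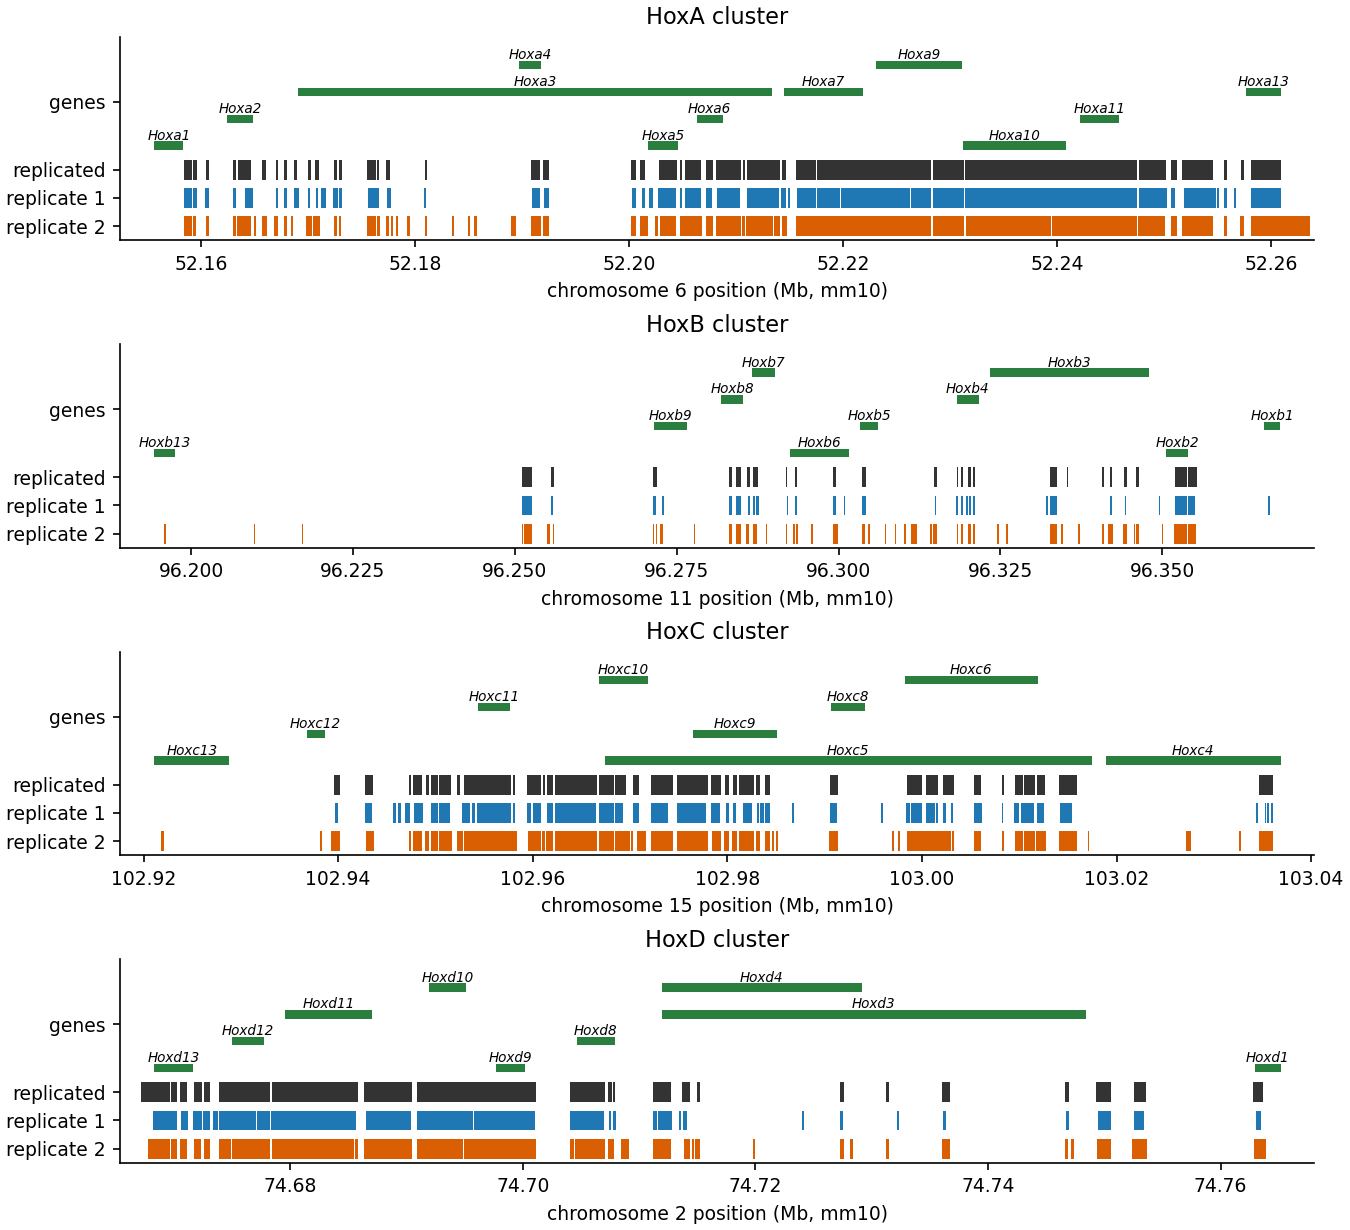
Maps of the 4 Hox clusters in mm10 coordinates, with the replicated peaks, the peaks of each replicate and the Hox genes drawn to scale. The HoxA map is the most densely filled (57.1% of bases covered) and the HoxB map the least (8.54%).

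The mark was broad at many, but not all, limb transcription factor and Hox genes. The bases covered within 5 kb on either side of the start of the gene averaged 1491 bp over all marked protein-coding genes. HoxA genes averaged 6920.3 bp ± 3371 (SD over genes), HoxD genes 5929 bp ± 3200.0, HoxC genes 5292 bp ± 3045 and limb transcription factors 4623 bp ± 2560. The limb transcription factors averaged 4380.2 bp in replicate 1 and 4876 bp in replicate 2. Each of these 4 lists exceeded random lists of marked genes (permutation test, two-sided, p = 2e-05, the smallest the permutations can give, adjusted p = 8.4e-05). Lmx1b, which sets dorsal identity, was covered over all 10001 bp of its window, Tbx5 over 8792 bp (8846 ± 195 over 2 replicates) and Meis2 over 8868 bp. At the other end Alx1 was covered over 344 bp, Lhx2 over 789 bp and Osr1 over 1087 bp, below the mean of all marked genes.

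The cell cycle, housekeeping, limb signalling and ribosomal protein lists were also broader than other marked genes, but by less. Cell cycle genes averaged 2407 bp (permutation p = 0.00102, adjusted p = 0.00306), housekeeping genes 2329 bp (permutation p = 0.00262, adjusted p = 0.00611), limb signalling genes 2238 bp (permutation p = 0.00044, adjusted p = 0.00154) and ribosomal protein genes 2236 bp (permutation p = 2e-05, adjusted p = 8.4e-05). Marked genes were narrower in the central neuron list, at 600.3 bp (permutation p = 0.0023, adjusted p = 0.00604), the blood list, at 762.9 bp (permutation p = 0.0112, adjusted p = 0.0234), and the ectoderm list, at 917.5 bp (permutation p = 0.0181, adjusted p = 0.0346). All these tests were two-sided. The blood and ectoderm lists lost the difference in replicate 2's own peaks (permutation adjusted p = 0.146 and 0.118), against CpG-matched lists (permutation adjusted p = 0.537 and 0.0656) and with a −log10 q of at least 5 (permutation adjusted p = 0.112 and 0.172). The central neuron list lost it only with a −log10 q of at least 5 among the alternatives run (permutation adjusted p = 0.99). In that setting only 5% of its 20 genes were marked, so the test could hardly have called a difference. Marked lymphocyte and chemosensory genes were narrower in replicate 2's own peaks (permutation adjusted p = 0.0344 and 7e-05), and endothelial, heart and chemosensory genes were in replicate 1's own peaks (permutation adjusted p = 0.0474, 0.0143 and 0.000945). HoxB genes averaged 1682 bp (permutation adjusted p = 0.678) but were narrower than other marked genes when bases were counted within 2 kb (669.3 bp, permutation adjusted p = 0.0196). The other 9 lists were not called in the replicated list either. Some held few marked genes, 2 each for liver and gut and chemosensory genes and 3 each for pluripotency and lymphocyte genes. In such lists a difference could be missed. The genes with the most covered bases outside the lists were Tnrc18 (9948 bp), Prdm16 (9899 bp), Zadh2 (9053 bp), Bahcc1 (9025 bp), Tshz1 (9004 bp) and Pdgfra (8803 bp), a receptor gene of mesenchymal cells. Zadh2 and Tshz1 are neighbours that share a start peak, so they stand for the same covered stretch.

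Genes of 1 Hox cluster share windows and peaks, so random lists of scattered genes give p-values that are too small for them. Each cluster was therefore also set against every run of as many neighbouring marked genes on a chromosome. The HoxA and HoxD lists are not runs themselves, since other annotated genes lie between their members, and each was counted as a further run in its p. Of 13432 runs 5 were as broad as HoxA, and all 5 held a Hox gene (exact enumeration, two-sided p = 0.000893, adjusted over the 4 clusters 0.00316). HoxD (exact p = 0.00178) and HoxC (exact p = 0.00237) also exceeded the runs (adjusted p = 0.00316 each), and HoxB did not (exact p = 0.548).

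**Figure D3:**
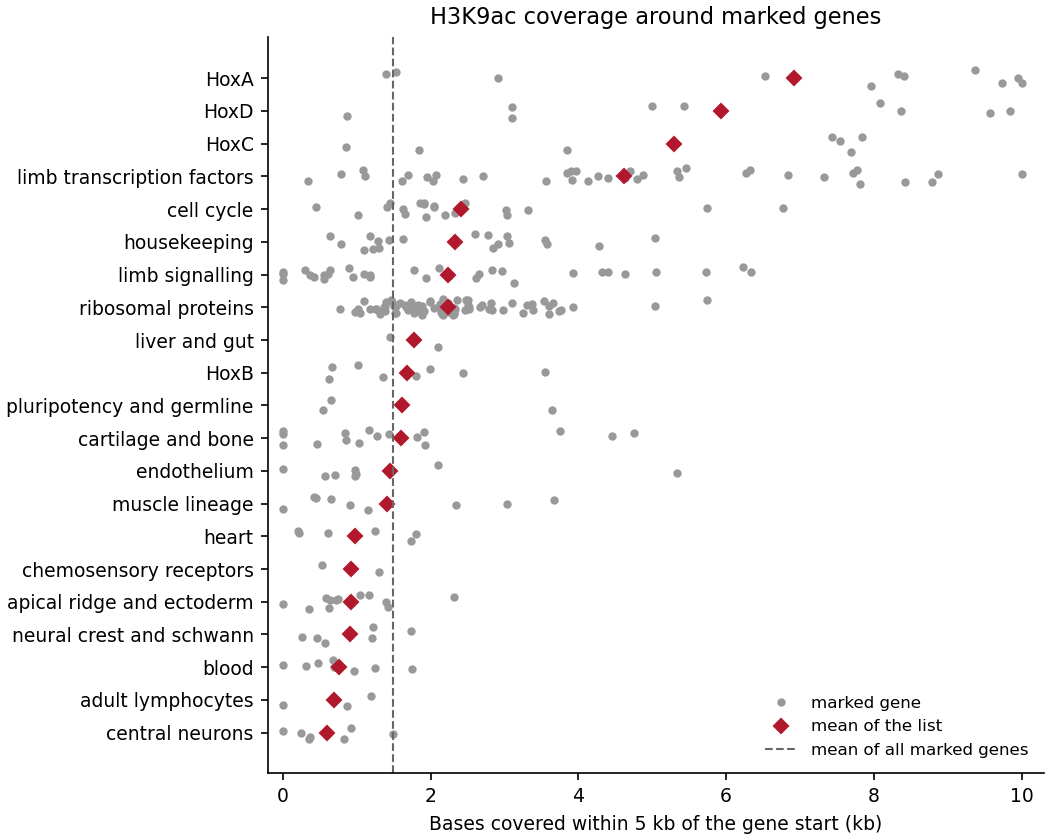
Bases covered by H3K9ac peaks within 5 kb on either side of the gene start, as points for the marked members of each gene list, with the list mean as a diamond and the mean of all marked genes as a dashed line. HoxA, HoxD, HoxC and limb transcription factors lie highest, with means between 4623 and 6920.3 bp.

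Peaks away from promoters were more frequent near limb transcription factors and 3 of the Hox clusters than near random genes. Of the 30298 replicated peaks 8453 (27.9%) lay over 2 kb from every annotated start, with a median width of 316 bp and a median signal of 3.35. Limb transcription factors had 5.27 ± 5.33 such distal peaks (mean ± SD over 37 genes) within 100 kb of their start, against 1.28 for random lists (permutation test, two-sided, p = 2e-05, the smallest possible, adjusted p = 0.00014). The replicates' own longer lists gave 8.19 and 13 for these genes. Counts rose there for other lists too, to 3.68 and 7.38 for limb signalling genes, so these values cannot be set against 1.28. In the replicated list Prrx2 had 24 distal peaks, Lmx1b 19, Tbx4 13, Tbx2 12 and Tbx5 10, while the median of the limb transcription factors was 3. These windows are shared with neighbours: Tbx2 and Tbx4 lie within 100 kb of each other, and Ntmt1 and 1700001O22Rik, close to Prrx2, had 28 distal peaks each. HoxC genes had 14.3 on average (permutation p = 2e-05, adjusted p = 0.00014), HoxD genes 4.89 (permutation p = 0.00348, adjusted p = 0.0146) and HoxA genes 4.64 (permutation p = 0.00206, adjusted p = 0.0108). HoxB genes had 3.60 (permutation p = 0.0224, adjusted p = 0.0523). In replicate 2's own peaks HoxD genes did not pass (8.56 distal peaks, permutation adjusted p = 0.266) and HoxB genes did (13.6, permutation adjusted p = 0.00764). Against runs of neighbouring genes only HoxC remained above the rest (exact enumeration, two-sided, p = 0.00147, adjusted p = 0.00588), while HoxA and HoxD did not (adjusted p = 0.165 each).

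Cartilage and bone genes had 2.86 distal peaks on average (permutation test, two-sided, p = 0.0153, adjusted p = 0.0458), with 17 near Comp, and ribosomal protein genes had 2.11 (permutation p = 0.00546, adjusted p = 0.0191). The cartilage result was lost in the peaks of either replicate alone and under 5 other alternatives, with permutation adjusted p between 0.0524 for covered bases and 0.485 for a −log10 q of at least 5 (0.476 peaks). The ribosomal protein result was lost under 5 alternatives, with permutation adjusted p between 0.0586 for covered bases and 0.725 for a −log10 q of at least 5 (0.317 peaks). Chemosensory receptor genes had fewer distal peaks than random lists, at 0.121 (permutation p = 2e-05, adjusted p = 0.00014). Members that are neighbours share windows, so this p may be too small, and the list was not compared with runs of neighbouring genes. The other 13 lists did not differ, the nearest being housekeeping genes at 2.89 (permutation adjusted p = 0.0501, and 0.0494 in replicate 1's own peaks). Limb signalling genes averaged 1.82 (permutation adjusted p = 0.279). The protein-coding genes with the most distal peaks were G430095P16Rik (31), Ahdc1 (30), and Lyl1, Nacc1 and Trmt1 (29 each), and of these G430095P16Rik, Lyl1, Nacc1 and Trmt1 are neighbours on chromosome 8 that share peaks.

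Across the genome the mark lay mainly at transcript starts. Of 30295 replicated peaks on the chromosomes 20002 (66.0%, 95% Wilson interval 65.5 to 66.6) lay within 1 kb of an annotated start, in 5.88% of the genome. These held 81.6% of all covered bases, with a median width of 762 bp and a median signal of 6.70. Introns held 15.4% of peaks, intergenic sequence 13.6% and exons 4.998%, with median signals between 3.33 and 3.50. The highest signals at protein-coding starts were at Bicral (40.4), a chromatin remodelling subunit gene, Tnpo1 (40.2), Hoxa9, Hoxa10 and Hoxa11 (39.9, a shared peak) and Polr2m (39.1). In the replicates' own longer lists the share at starts was 49.6% and 38.8%.

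Of 21938 protein-coding genes 13635 (62.2%, 95% Wilson interval 61.5 to 62.8) were marked, and the replicates' own peaks gave 64.8% ± 2.14 (SD, n = 2). Long intergenic non-coding RNA genes were marked in 12.9% of cases, antisense genes in 32.6% and processed pseudogenes in 0.986%. Counting only those over 2 kb from protein-coding starts, the shares were 7.73%, 9.74% and 0.716%. Over all genes of these types the peaks of replicates 1 and 2 gave 15.3% and 18.9%, 35.7% and 40.4%, and 1.57% and 2.68%. Promoters rich in CpG dinucleotides, a class that holds most housekeeping genes, were marked in 95.6% of 9740 genes, against 35.4% of the 12198 other genes (odds ratio 39.9). The corresponding shares were 95.7% and 37.5% in replicate 1 and 97.0% and 41.9% in replicate 2. Fisher's exact test of this difference gave a p too small to be represented. The intervals cover counting error only.

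The promoters with the strongest peaks were called in both replicates, and most of the difference between the replicates lay in weak peaks away from promoters. Of replicate 1's peaks 60.2% overlapped a peak of replicate 2 by at least 1 bp, and of replicate 2's longer list 38.3% overlapped replicate 1. In the decile of each list with the lowest p-values the overlap was 100% in both directions, and 97.8% and 97.7% of these peaks lay at starts. In the decile with the highest p-values the overlap was 27.2% for replicate 1 and 11.3% for replicate 2, and 24.0% and 19.8% lay at starts. Signal ranked alike across the 29651 overlapping peaks of replicate 1 and their partners (Spearman's rho 0.740, across peaks, which are not independent replicates), and the covered bases had a Jaccard index of 0.452. Marked genes overlapped far more than peaks did: 13602 protein-coding genes were marked in both replicates, 285 in replicate 1 only and 950 in replicate 2 only.

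The unshared peaks were narrow, with median widths of 212 bp in replicate 1 and 215 bp in replicate 2. The strongest peaks without a partner were, in replicate 1, an intergenic peak at 180226289 to 180226780 on chromosome 1 (signal 6.90) and a peak 45354 bp from Igf1 (6.55). In replicate 2 they were at Snord118 within Tmem107 (8.77), in intergenic sequence on chromosome 10 (8.01), in Gm41505 (7.69) and at the start of Kitl (7.37). All 10 of the strongest unshared peaks, 5 per replicate, were overlapped by the list called on both replicates together.

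**Figure D4:**
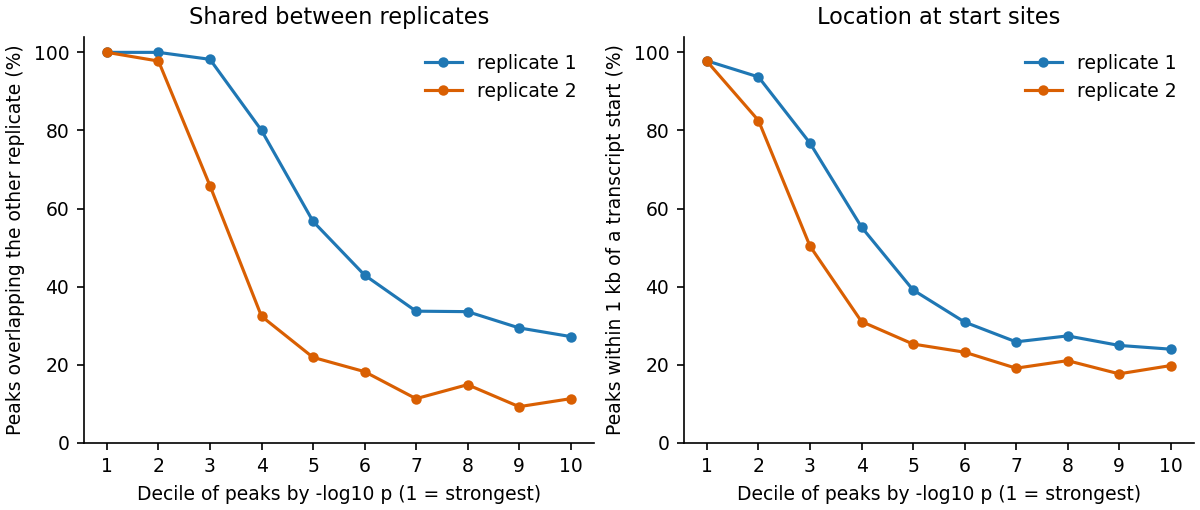
Percentage of each replicate's peaks that overlap the other replicate, and percentage at transcript starts, by decile of the list from the lowest to the highest p-value. Overlap drops from 100% to 27.2% in replicate 1 and to 11.3% in replicate 2.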

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

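The results in this part were picked out after the data were seen, and no explanation was tested for them. In the peaks called on both replicates together, 14 peaks had a −log10 q of at least 5 and were still outside the replicated list that the comparisons of genes and locations use. The strongest lay at 3567960 to 3568162 on chromosome 8 at the start of C330021F23Rik, with a −log10 q of 6.73, and overlapped a peak of replicate 2 only. Another, 45381 bp from the growth factor gene Igf1 on chromosome 10, had a −log10 q of 5.88 and overlapped replicate 1 only.

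Peaks also lay on sequences of the assembly outside its assembled chromosomes, which the comparisons of genes and locations did not use. There were 7 in replicate 1, 4 in replicate 2, 5 in the list called on both together and 3 in the replicated list.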

How the results depend on the processing

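Hox cluster coverage was added, and peaks overlapping both replicate lists and runs of neighbouring genes were tried as alternatives, after seeing the data. Among the main results 210 alternative values stayed on the same side or within the spread. Of the rest 33 moved beyond it, 14 lost a call, 4 gained a call and 1 reversed. The cause of these changes was not tested. With an overlap of 50% of the shorter peak 55.5% of replicate 1 and 34.9% of replicate 2 were shared, with 50% of each peak 40.1% and 27.5%, and with equal numbers of top peaks 55.8% and 50.5% (Jaccard 0.502). Ranking all peaks by −log10 p gave a rho of 0.756. A −log10 q of at least 5 left 17217 and 18553 peaks in replicates 1 and 2, 16462 in the pooled and 16448 in the replicated list. It gave 90.4% and 79.4% shared, Jaccard 0.691, rho 0.773, 87.1% of peaks at starts, 55.6% of genes marked and CpG odds ratio 25.8. It also gave HoxD marking of 88.9%, limb signalling of 70.6%, 8 lists marked less often, 0 lists narrower, and Hox coverage of 50.9% (A), 5.31% (B) and 37.5% (D). The pooled list put 58.2% of peaks at starts, and without each replicate in turn this was 38.8 to 49.6%, marked genes 63.3 to 66.3%, narrower lists 3 to 6, HoxA coverage 56.0 to 60.3% and HoxB coverage 8.09 to 12.2%. HoxD marking stayed at 100% but lost its call with the pooled list (exact adjusted p = 0.0546), a 2 kb window (exact adjusted p = 0.0597), CpG-matched lists (permutation adjusted p = 1) and each replicate alone (100 to 100%). HoxA marking, also 100%, lost its call with CpG-matched lists (permutation adjusted p = 0.92), where 4 lists were marked more often and 1 was narrower. The CpG-matched comparison could not have called HoxA, HoxD or the cell cycle list higher, since even full marking did not pass. HoxB breadth reversed to below other genes within 2 kb (669.3 bp, permutation adjusted p = 0.0196). HoxB distal peaks passed the threshold with the pooled list (7.10), within 50 kb (2.80), as covered bases (1914 bp) and without replicate 1 (range 5.30 to 13.6). HoxA distal peaks lost their call within 50 kb (1.82), and HoxA (4.64) and HoxD (4.89) did so against lists matched on nearby starts, where 3 lists stayed above, and against neighbouring runs. HoxD distal peaks also lost it without replicate 1 (range 8.56 to 10.2, permutation adjusted p = 0.266). Of the values of the other lists 323 stayed on the same side, 25 lost and 12 gained a call. Merging overlapping peaks moved nothing, since no list held any. Unknown depth limits any statement on genes without a peak.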

Other observations

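The genes and peaks of the next 2 paragraphs were chosen after their values were seen, as were the tests of list length and random placement, while what the tests of the X chromosome and of HoxB would show was set down before their results. Several non-coding RNA genes had strong start peaks away from the starts of protein-coding genes. Mir17hg, the host gene of a microRNA cluster that promotes proliferation, had a signal of 30.2 (28.2 and 30.1 in replicates 1 and 2), the snoRNA host Snhg6 had 25.4, and the abundant nuclear RNA gene Malat1 had 17.8. Dnm3os, the host of microRNAs expressed in mesenchyme, had 15.1, and Mir670hg had 19.8. The antisense gene Gm47071, whose start lies 9.94 kb from that of the hindlimb gene Pitx1, had 16.9.

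The 12 strongest peaks over 2 kb from every start, ranked by −log10 q, lay in or near genes of several functions. The first, at 27337785 to 27340104 on chromosome 12, was within Sox11, a transcription factor gene of embryonic progenitors (signal 26.1), 2470 bp from its start. Others lay at 86487614 to 86488854 on chromosome 1, 37.9 kb from Ptma (23.9), at 119056331 to 119057502 on chromosome 11, 15.4 kb from the Polycomb gene Cbx8 (18.8), at 8623302 to 8625192 on chromosome 11 within Tns3 (19.4), and at 30513255 to 30516037 on chromosome 3 within Mecom (13.4). Each of these 5 peaks overlapped both replicate lists.

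With the X-linked genes Hprt and Pgk1 at the bottom of the housekeeping list, promoters on the X chromosome were compared with autosomal ones, and among CpG-rich genes 87.2% were marked on the X chromosome and 95.8% on autosomes (Fisher's exact test, two-sided, p = 1.75e-07). Near-identical copies do not account for it, because among genes with unique start regions the share was still 89.5% (95% Wilson interval 84.6 to 92.9) against 96.9%. Signal at the marked genes with unique starts had a ratio of 0.622 between X chromosome and autosomal medians (7.04 and 11.3, permutation test, two-sided, p = 2e-05, the smallest possible), and of 0.623 and 0.5997 in replicates 1 and 2. What the signal is relative to is not given in the sources used here, so the ratio ranks the peaks of a list and is no measure of dose. Lower signal on the X may leave more X-linked promoters below calling, and a single X chromosome in males and an inactive X in females are candidate sources that no group of this design could test.

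HoxB stood apart from the other clusters, with 8.54% of its bases covered. The long stretch between Hoxb13 and Hoxb9 is not enough to account for this, since Hoxb1 to Hoxb9 alone were covered over 13.1% (15.6% ± 4.60, SD, n = 2), below the 35.7% of HoxC. Sequence that cannot be mapped uniquely is not enough either, as 95.2% of 36-base words in HoxB were unique, against 98.4 to 99.2% in the other clusters. With both of these set aside, low acetylation of HoxB in these limbs stays as a hypothesis, and no biological explanation was tested.

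Replicate 2 had more peaks than replicate 1. With equal numbers of top peaks 50.5% of replicate 2 was shared, up from 38.3%, and the gap between the replicates' shared percentages closed from 21.9 to 5.35 points. Lists of equal length share similar numbers of peaks, so this closing says nothing about the cause. The comparison never shortens replicate 1 and had no outcome that could exclude list length, so no conclusion is drawn from it. Only 60.2% of replicate 1's peaks overlapped the longer list, so that list did not simply contain the shorter one. Among replicate 1's unshared peaks 2.03% had a −log10 q of at least 5. Whether list length was a source of the unshared peaks stays open. Replicate 2's unshared peaks were not all scattered at random, since 19.7% lay at starts against a mean of 6.97% and a highest value of 7.30% in 100 random placements. Part of them may be weak marks at promoters, a difference in depth stays open, and no biological explanation was tested.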
